A study of Mus musculus with 6 samples.

How the data were processed

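CUT&RUN for H3K27ac was performed by the submitters on PCM-1 sorted nuclei of mouse left ventricle, and 6 peak lists, 3 per genotype, were analysed here. The submitters' processing notes name BWA, MACS2 and the build mm10, with versions not given in the sources used here. The lists have the columns of a MACS2 narrow peak file and were deposited for each library separately, so no pooling of replicates entered them. The deposited lists give for each peak a score, a fold enrichment at the summit, and the −log10 of a p-value and of a q-value, all set by the authors' peak caller. These values belong to the authors and were used only to describe, rank and filter peaks within a list. Groups and replicate numbers came from the sample titles.

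The lists hold no read counts, so the depth is not stated in them. Fold values in each library were whole multiples of a constant, within 0.02, for 100% of peaks. This gave the background pileup of each library, 1.48, 1.48 and 1.23 reads in WT replicates 1, 2 and 3 and 1.65, 0.558 and 1.38 in HOM replicates 1, 2 and 3. A Poisson tail with that background returned the deposited −log10 p within 4.4e-05 in all libraries (peaks below 200). Divided by the smallest peak width (177, 165, 162, 166, 57 and 171 bp in the same order), which is taken here as the fragment length of the peak caller, the background gave 8.36, 8.98, 7.6, 9.94, 9.8 and 8.07 per kb. This quantity is proportional to the number of tags if that reading of the width holds.

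Genes came from the RefSeq table of GRCm38.p6, the assembly that mm10 names, and 241 of 241 listed gene symbols matched. The table gives no strand, so the planned window of 1 kb around the transcription start was replaced by windows of 1 kb around both ends of the annotated gene. Positions are 1-based. Peaks were united per library for covered lengths, and touching peaks of the 6 libraries were merged into regions. Windows for the flank percentile were non-overlapping, with a WT covered length within a factor of 1.5. A constant of 0.5 was added to counts in logits.

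Differences in log10 peak number, log10 covered length, covered length in the interval, flank coverage and marked share per list were tested with two-sided exact permutation tests over the 20 assignments of libraries. Overlap and counts of regions or genes specific to a genotype were set against the 10 splits. Tests, the 14 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named every listed gene within 250 kb of the interval, in each other list the genes marked in all libraries of one genotype only or otherwise the 3 most and the 3 least often marked, and outside the lists up to 10 genes per direction. Where a list's members are named as marked in most libraries, ties were taken alphabetically. Some genes that the rule named are not reported here.

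Alternatives were the 50% stronger peaks of each list, lists limited to the shortest, each library left out, the replicate numbers as a block, chromosomes 1 to 19 and X, other definitions of overlap and regions, windows of 500 bp and 2 kb at gene ends, flanks of 100 and 500 kb, constants of 100 and 10000 bp, stitching over 5 and 20 kb, and an interval widened by 20 kb. After the data were seen, 3 more were added: 5 libraries without HOM replicate 2 at equal length, a −log10 q of at least 5 in every library, and the whole gene with 1 kb on each side. On simulated lists of 20000 regions with 200 planted per direction, the region count recovered 200 and 200 of them, with totals of 211 and 209. Planted regions were set as called in every library of 1 genotype and in none of the other. All simulated lists had the same call rate. This therefore tested the counting alone and says nothing of lists of unequal length. Coverage and overlap were tested on simulated data in 200 trials with 0 mismatches. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.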

Results

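Acetylation of histone H3 at lysine 27, a mark of active promoters and enhancers, was profiled by CUT&RUN in nuclei sorted for PCM-1, a protein of cardiomyocyte nuclei, from the left ventricle of FVB mice aged 8 to 12 weeks. The mice were wild type (WT) or carried a CRISPR deletion of Nppa and Nppb (HOM), the neighbouring genes of atrial and B-type natriuretic peptide. Each genotype had 3 libraries, and each library had its own list of called peaks. Nothing in the labels says that the libraries came from separate mice, so the p-values measure the spread between these samples, which may be technical. With 3 libraries against 3, the smallest two-sided exact permutation p is 0.1, so no comparison of all 6 libraries could pass 0.05.

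The interval from Nppb to Nppa carried peaks in WT libraries and none in HOM libraries. It spans positions 147985786 to 148002074 of chromosome 4 in mm10. The labels do not give the ends of the deletion, so this interval stands in for it. WT replicates 1, 2 and 3 had 1, 2 and 4 peaks there, covering 321, 734 and 2175 bp. HOM replicates 1, 2 and 3 had 0 peaks there. In WT replicates 2 and 3 some of these peaks lay on Nppb. No WT peak overlapped Nppa, which starts at 148000722. The nearest peaks below it ended at 148000466, 148000560 and 148000647 in WT replicates 1, 2 and 3, between the genes. Mean covered length was 1076.7 ± 973 bp (SD, n = 3) in WT and 0 bp in HOM (n = 3), with an exact permutation p of 0.1. Without WT replicate 3 the difference was -527.5 bp, and over the interval widened by 20 kb on each side it was -745 bp, with an exact permutation p of 0.8. HOM replicates 1 and 3 shared a stretch without peaks from position 147982651 to 148003015, in which the WT lists had 1, 3 and 5 peaks. HOM replicate 2 had no peak between positions 147431535 and 149757064, so its empty interval says nothing of the deletion. When each list was limited to its 1462 strongest peaks, the length of the shortest list, no library had a peak in the interval.

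**Figure D1:**
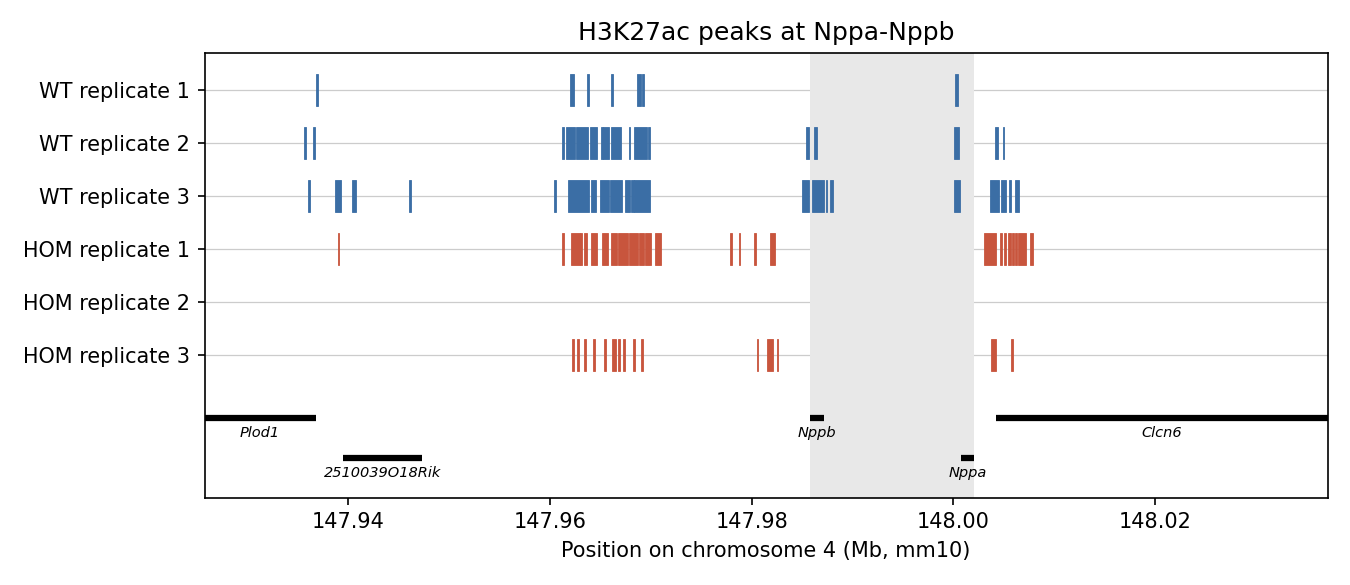
Peaks of the 6 libraries around Nppa and Nppb, drawn to scale as blocks against position on chromosome 4 (Mb, mm10), with WT in blue, HOM in red, annotated protein-coding genes in black and the interval from Nppb to Nppa in grey. The interval holds 1, 2 and 4 peaks in the WT libraries and 0 in the HOM libraries, and HOM replicate 2 has no peak in the drawn region.

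Around the missing genes, acetylation remained in HOM replicates 1 and 3. A cluster of peaks between positions 147960412 and 147971037, between 2510039O18Rik and Nppb, covered 1345, 6517 and 7212 bp in WT replicates 1, 2 and 3, and 6930 and 2345 bp in HOM replicates 1 and 3. Peaks at the lower end of Clcn6, a chloride transporter gene, and between it and Nppa lay in a cluster from 148000052 to 148007931. This cluster held 8 peaks covering 3373 bp in HOM replicate 1 and 2 peaks covering 699 bp in HOM replicate 3. In WT replicates 1, 2 and 3 it held 1, 3 and 5 peaks covering 321, 1063 and 2438 bp, including those below Nppa.

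In the 250 kb on each side of the interval, peaks covered 7728, 35826 and 47889 bp in WT replicates 1, 2 and 3, and 29938, 0 and 8655 bp in HOM replicates 1, 2 and 3. Relative to the length covered genome wide, this was 1155, 1133 and 860 bp per Mb in WT, and 1741, 0 and 1906 bp per Mb in HOM. The mean fold enrichment of these peaks, as given by the authors, was 4.72, 5.29 and 5.97 in WT, and 5.14 and 4.96 in HOM replicates 1 and 3. On the log2 scale with 1000 bp added, the value was 10.10 ± 0.29 in WT and 11.20 ± 0.47 in HOM (SD, n = 3 each), a difference of 1.09 with an exact permutation p of 0.1. The value of HOM replicate 2, 11.72, was set by the added constant, since that library had no peak there. With 100 bp added the difference was -0.0031, with 10000 bp it was 2.11, and without HOM replicate 2 it was 0.83. With that library left out and the other lists at equal length it was 0.67, and with all lists limited to the shortest 0.45 (exact permutation p = 0.4). Without HOM replicate 2, 98.9% of 370 windows of the same length and similar WT coverage had a lower difference, against 95.1% with it. The median difference of these windows was 0.163 without that library, beside 0.83 at the locus. With it the median was 0.725, beside 1.09 at the locus, so windows elsewhere also gave positive differences.

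Genes near the interval were marked in both genotypes, a gene being marked when a peak lay within 1 kb of either annotated end. Mfn2, which encodes a protein of mitochondrial fusion, was marked in 3 WT and 2 HOM libraries. Clcn6 was marked in 2 WT and 2 HOM libraries. Plod1, Agtrap and Fbxo6 were each marked in 3 WT libraries and in 1 HOM library, and Miip, Fbxo2 and Fbxo44 each in 2 and 1. The gene 2510039O18Rik was marked in 1 library of each genotype. Draxin, Mad2l2 and Disp3 were marked in none. Nppb was marked in 2 WT libraries and 0 HOM libraries. Nppa was marked in 3 WT libraries and in HOM replicate 1, where the peak lay above the gene, starting at position 148003016. These counts are for the full lists. With HOM replicate 2 left out and the other lists at equal length, Clcn6 was marked in 0 WT and 2 HOM libraries. Fbxo6 was then marked in 3 WT and 0 HOM libraries, the opposite direction, and Mfn2 in 3 and 2. Differences at single genes were not tested.

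The question of a super enhancer at the locus was addressed by joining peaks over gaps up to 10 kb and ranking the joined domains by covered length within each library. The leading domain within 50 kb of the interval was the cluster between 2510039O18Rik and Nppb in all 5 libraries that had one. It ranked 1155 of 7593 domains in WT replicate 1, 998 of 16686 in WT replicate 2 and 1697 of 20856 in WT replicate 3. It ranked 321 of 12362 domains in HOM replicate 1, where it extended to position 147982327, and 325 of 5977 in HOM replicate 3. In WT it stood at 9.78 ± 4.83% from the top (SD, n = 3). Ranks from lists of different lengths cannot be compared between libraries, so neither a change nor its absence was read from them.

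Genome wide, WT lists held 21340, 72362 and 106605 peaks in replicates 1, 2 and 3, and HOM lists held 48102, 1462 and 15184. The covered lengths were 6.69, 31.6 and 55.7 Mb in WT and 17.2, 0.296 and 4.54 Mb in HOM, with median peak widths of 241, 286 and 291 bp and of 260, 84 and 232 bp. The log10 peak number was 4.74 ± 0.365 in WT and 4.01 ± 0.773 in HOM (SD, n = 3 each), a difference of -0.729 with an exact permutation p of 0.2. The log10 covered length in bp was 7.36 ± 0.476 in WT and 6.45 ± 0.9 in HOM (SD, n = 3 each), a difference of -0.903 with an exact permutation p of 0.2. Without HOM replicate 2 these differences were -0.307 and -0.411. Without HOM replicate 1 they were -1.07, with an exact permutation p of 0.1, the smallest possible, and -1.29, with an exact permutation p of 0.2. With lists limited to the shortest, the difference in log10 covered length was -0.505. WT replicate 1 and HOM replicate 1 had 111 and 112 peaks on the Y chromosome below 80 Mb, and between these 2 libraries the difference in log10 peak number was 0.353. Among the other 4 libraries it was -1.27, and -0.762 without HOM replicate 2, so the direction was not the same in both sets.

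**Figure D2:**
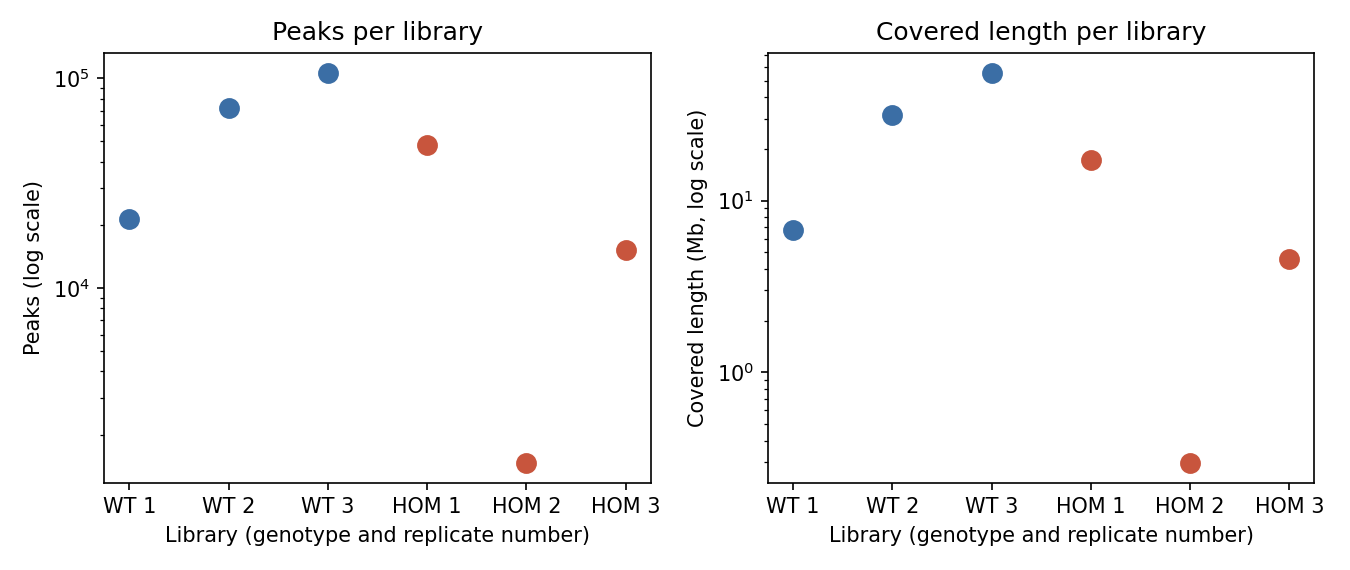
Number of peaks (left) and covered length in Mb (right), both on log axes, with 1 point per library, WT in blue and HOM in red. Peak numbers run from 1462 in HOM replicate 2 to 106605 in WT replicate 3, and the genotypes overlap.

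With all 6 libraries, peak positions did not separate by genotype beyond other groupings. The mean Jaccard index, shared over united length, was 0.155 within genotypes and 0.141 between them. The difference of 0.014 was matched or exceeded in 3 of the 10 splits of the 6 libraries, the real one included. The highest index joined WT replicates 2 and 3 (0.42), and the index of HOM replicate 1 was higher with WT replicate 2 (0.339) than with HOM replicate 3 (0.169). Unequal covered lengths limit the index, so these pairs do not rank likeness between libraries. Of HOM replicate 3 peaks, 77.8% overlapped a peak of HOM replicate 1 and 90.8% a peak of WT replicate 2. The sign of the difference between the mean indices turned without WT replicate 2 (-0.0468) or WT replicate 3 (-0.054). Without HOM replicate 1 the difference was 0.111, which none of the other groupings of the remaining libraries matched. That is a share of 0.1 of the splits, the smallest possible, counting only differences as high. The HOM side then held the 2 shortest lists, and the index of HOM replicate 2 was at most 0.0565 with any library. This value therefore cannot be told apart from an effect of list length. The difference was 0.0305 without WT replicate 1 and 0.0314 without HOM replicate 3.

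Of 114976 merged regions, 1181 were called in all WT libraries and no HOM library, and 2 in all HOM libraries and no WT library. By gene, 237 of 21631 protein-coding genes were marked in 3 WT and 0 HOM libraries, and 0 in the reverse pattern. Outside the gene lists, the marked genes with the highest mean percentile of the authors' peak score were Agtpbp1 on chromosome 13 (95.7), Pptc7 on chromosome 5 (90.2), the ribosomal protein gene Rpl29 on chromosome 9 (89.5), and Ginm1 and the mitochondrial ribosomal protein gene Mrpl43 (88.7 each). They were followed by Glg1 (88), Ctns and its neighbour Shpk (87.6 each), Zwint (86.9) and Gypc (86.4). Without HOM replicate 2 the region counts were 1198 and 25 and the gene counts 241 and 0. With that library left out and the other 5 lists limited to 15184 peaks each, 498 regions were in 3 WT and 0 HOM libraries and 173 in the reverse pattern, and the gene counts were 110 and 30. Of the genes named above, Glg1, Ctns and Shpk were not among these 110, and the others were. At 15184 peaks each, the lists still covered 5.27, 14.2 and 24.2 Mb in WT, and 8.53 and 4.54 Mb in HOM replicates 1 and 3. Their lowest −log10 q ran from 1.2 in HOM replicate 3 to 10.7 in WT replicate 3. Equal peak number thus did not equalise covered length or stringency, and the higher WT counts cannot be told apart from these. Without WT replicate 1 the WT counts were 17680 regions and 2063 genes, and without HOM replicate 1 they were 5218 and 1261.

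Genes of the working cardiomyocyte were marked in most libraries of both genotypes. Of 20 contractile and sarcomere genes, 16, 19 and 20 were marked in WT replicates 1, 2 and 3, and 20, 0 and 16 in HOM replicates 1, 2 and 3. The cardiac actin gene Actc1, Csrp3 and the desmin gene Des were marked in 3 WT and 2 HOM libraries. Of 20 ion channel and calcium handling genes, 14, 19 and 19 were marked in WT and 18, 0 and 15 in HOM. The calcium pump gene Atp2a2, Camk2d and the calsequestrin gene Casq2 were marked in 3 WT and 2 HOM libraries, and Cacnb2 in none. Over the whole gene with 1 kb on each side, 18, 20 and 20 of these genes had a peak in WT and 20, 2 and 19 in HOM. Cacnb2 thus had a peak within that range in WT replicates 2 and 3 and HOM replicate 1. Of 20 genes of fatty acid and energy metabolism, 16, 18 and 20 were marked in WT and 17, 0 and 16 in HOM. Acaa2, Acadl and Acadm, enzymes of fatty acid oxidation, were marked in 3 WT and 2 HOM libraries, and Ppargc1a in 1 WT library. Of 20 cardiac transcription factors, 11, 16 and 18 were marked in WT and 16, 1 and 12 in HOM. Esrra, Gata4 and Gata6 were marked in 3 WT and 2 HOM libraries, and Hand1 and Tbx5 in none. Over the whole gene with 1 kb on each side, 18, 19 and 19 transcription factors had a peak in WT and 19, 5 and 18 in HOM. At least 1 of Hand1 and Tbx5 thus had a peak within that range, so unmarked gene ends do not mean a gene without acetylation.

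Of 20 stress and hypertrophy genes, 9, 15 and 17 were marked in WT and 14, 0 and 8 in HOM. Ccn1, Jun and Myc were marked in 3 WT and 2 HOM libraries, and Acta1 in none. Among 16 genes of the natriuretic peptide and cGMP pathway, 1, 4 and 5 were marked in WT and 3, 0 and 0 in HOM. Prkg1, a cGMP-dependent kinase gene, was marked in 3 WT libraries and in 1 HOM library, Corin and Pde3a in 2 and 1, and Gucy1a1 in none. Of 12 atrial genes, 1, 1 and 2 were marked in WT and 1, 0 and 1 in HOM, and the recurrent member was Kcnj5. Of 26 genes of the Nppa-Nppb neighbourhood, 10, 16 and 19 were marked in WT and 15, 0 and 5 in HOM. This locus list includes the deleted Nppa and Nppb, so its counts do not describe retained neighbours alone. It also holds Vps13d, Dhrs3, Tnfrsf1b and Tnfrsf8, between positions 144871045 and 145315164 of chromosome 4, well outside the 250 kb flanks. Of 20 housekeeping genes, 7, 14 and 18 were marked in WT and 11, 0 and 4 in HOM, with Vcp in 3 WT and 0 HOM libraries.

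At gene ends, none of 12 fibroblast markers such as Col1a1, 13 endothelial markers such as Cdh5 and 20 genes of other organs such as Alb was marked in any of the 6 libraries. Over the whole gene with 1 kb on each side, an alternative added after the data were seen, 1, 4 and 8 endothelial markers had a peak in WT and 3, 0 and 1 in HOM, and 1, 3 and 3 fibroblast markers in WT and 2, 0 and 0 in HOM. Smooth muscle and pericyte markers were marked at 2, 3 and 4 of 10 in WT and 2, 0 and 1 in HOM, led by Cspg4 and Abcc9 with Myh11 in none. Of 12 immune markers, 0, 3 and 3 were marked in WT and 2, 0 and 1 in HOM, led by Spi1 and Cd68.

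**Figure D3:**
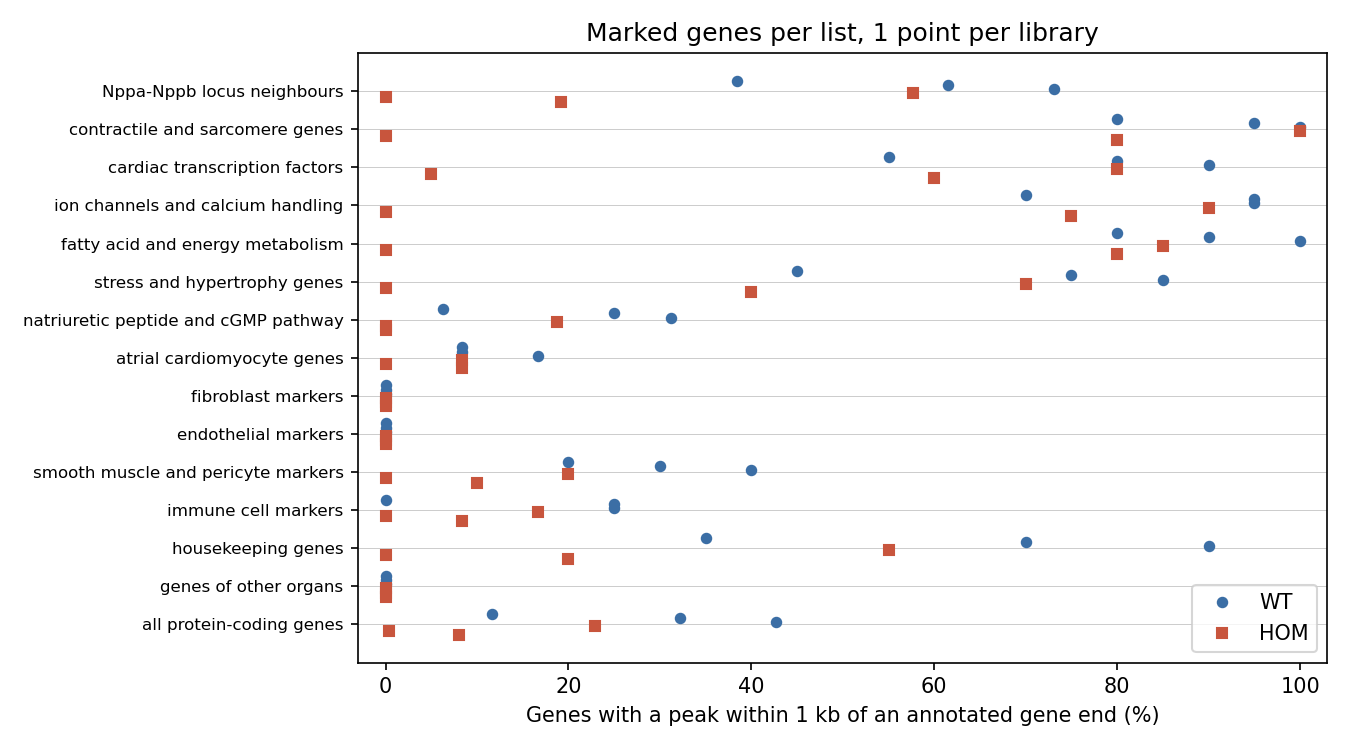
Percent of the genes of each list with a peak within 1 kb of an annotated gene end, 1 point per library, WT as blue circles and HOM as red squares, shifted vertically for visibility. HOM replicate 2 lies at 0 in all 14 lists except the transcription factors, and fibroblast, endothelial and other-organ genes lie at 0 in all libraries.

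No list's marked share gave an exact permutation p below 0.2 between genotypes. The difference in marked share ranged from -40 percentage points for housekeeping genes (65 ± 27.8% in WT and 25 ± 27.8% in HOM, SD, n = 3 each, exact permutation p = 0.2) to 0 for the unmarked lists. Smooth muscle and pericyte markers differed by -20 points (30 ± 10% in WT and 10 ± 10% in HOM, SD, n = 3 each, exact permutation p = 0.2). Over all 21631 protein-coding genes the share was 28.8 ± 15.8% in WT and 10.5 ± 11.5% in HOM (SD, n = 3 each), a difference of -18.4 points with an exact permutation p of 0.2. The difference was larger than the SD of either genotype for all protein-coding genes and for the housekeeping, smooth muscle and pericyte, locus, natriuretic pathway and atrial lists, and not for the other lists. The smallest Benjamini-Hochberg adjusted value over the 14 lists was 0.56. Relative to all protein-coding genes on the logit scale, the smallest adjusted value was 0.4. It was shared by several lists, among them transcription factors and immune markers, with differences of 0.586 and 1.55 and an exact permutation p of 0.1 each, the smallest possible, and lists without a marked gene, whose larger difference of 2.04 came from the share of all genes alone. With HOM replicate 2 left out and 15184 peaks per list, the relative differences of transcription factors and immune markers were 0.132 and 0.44, with an exact permutation p of 0.7 and 0.6. The difference of transcription factors was 0.108 with windows of 500 bp (exact permutation p = 0.6) and -0.629 with lists limited to the shortest (exact permutation p = 0.2), and that of immune markers was 0.802 without HOM replicate 2 (exact permutation p = 0.2). With 15184 peaks per list and without HOM replicate 2, the differences in marked share were -5 points for contractile genes, 3.33 for metabolism, -12.5 for stress genes and -3.33 for housekeeping genes. The difference largest in size was -13.3 points for smooth muscle and pericyte markers, with an exact permutation p of 0.1, the smallest possible, at 2, 2 and 3 of 10 genes in WT and 1 and 1 in HOM.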

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

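The alternatives with 5 libraries at equal length, a common −log10 q and whole genes were chosen after the data were seen. Over all results, 406 alternative values kept their direction or stayed within 1.5 times of the count, 28 turned and 33 moved. The 406 include lists without any marked gene, which have no direction to keep. They also include the replicate block, whose differences must equal the main ones, so the number does not measure robustness. No exact permutation or sign-flip test run here can reach 0.05, so a kept direction says nothing of significance. Where not stated, the cause was not tested.

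Leaving out 1 library each gave overlap differences from -0.054 to 0.111, turning without WT replicate 2 (-0.0468) and WT replicate 3 (-0.054). Regions in all WT and no HOM libraries ranged from 1198 to 17680 (fewer libraries make the pattern easier to meet), and the reverse from 3 to 25. The WT gene count ranged from 241 to 2063. On the logit scale relative to all genes, the locus list ranged from -0.0512 to 0.206 (-0.0246 without WT replicate 2, -0.0149 without HOM replicate 1), contractile genes from -0.763 to 0.78 (0.181 without WT replicate 3), ion channels from -0.473 to 0.341 and the natriuretic pathway from -0.259 to 1.3. The upper or lower ends of these last ranges that turned the sign, 0.78, 0.341 and -0.259, came without HOM replicate 2.

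With a constant of 100 bp the flank difference was -0.0031, because HOM replicate 2 has no covered bp there. With lists limited to the shortest, the difference in the interval was 0 bp, region counts were 53 and 4, gene counts 4 and 1, and the list differences for the natriuretic pathway, smooth muscle and immune markers were 0 points. The relative logits were then -0.629 for transcription factors, 0.0057 for metabolism, -0.938 for stress genes and -0.0033 for atrial genes. With 5 libraries at equal length, region counts were 498 and 173 and gene counts 110 and 30. List differences were 3.21 points for the locus, 3.33 for metabolism, 2.78 for atrial, 1.39 for immune and 0 for ion channel genes. Relative logits were 0.181 for ion channels, 0.314 for metabolism, -0.24 for stress genes, -0.0996 for the natriuretic pathway, -0.533 for smooth muscle and 0.0993 for housekeeping genes. With the 50% stronger peaks of each list there were 784 WT regions, and relative logits of 0.556 for ion channels and 0.564 for housekeeping genes. Regions merged over 500 bp numbered 752 and 0, and those covered over at least 0.5 of their length 360 and 0. Windows of 500 bp gave 0 points for immune markers and 0.071 for housekeeping genes, and windows of 2 kb gave -0.0025 for the locus list, the last 2 being relative logits. From 0 at gene ends, windows of 2 kb gave -5.56 points for fibroblast markers and -1.67 for genes of other organs, and whole genes with 1 kb gave -13.9 for fibroblast and -23.1 for endothelial markers. Wider windows can take in more peaks, but genes of other organs stayed at 0 over whole genes, and the cause was not tested.

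As a replicate block, same-numbered libraries gave the same differences, -0.729 in log10 peak number and 1.09 in flank coverage, as equal groups must. The exact sign-flip p was 0.5 and 0.25, and 0.25 is the smallest that 3 pairs allow, so the block could change no call. Correlations over regions of the deviations of same-numbered libraries from their genotype means were 0.0801, -0.173 and 0.0174. Those of differently numbered libraries ran from -0.234 to 0.301. This spread covers the same-numbered values, so they show no pairing but cannot exclude it. WT replicate 1 and HOM replicate 1, a same-numbered pair, had 111 and 112 peaks on the Y chromosome below 80 Mb. Whether the numbers pair the samples stays open.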

Other observations

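The tests on tag number, enrichment, the region beside the interval and the X share, the splits at equal list length and the description of joined domains were chosen only after the result was seen.

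Joined domains were ranked by covered length in the 5 libraries other than HOM replicate 2. Rbm20, which encodes a splicing regulator of titin, lay in the top 25 domains of all 5, at ranks 15, 1 and 1 in WT replicates 1, 2 and 3 and at ranks 6 and 11 in HOM replicates 1 and 3. Ank, Vps13d and Ppargc1b each lay in the top 25 of 4 of the 5 libraries. Gata4, a cardiac transcription factor gene, lay there in 3, as did Tns1. Predicted genes such as Gm15319 and Gm21119 lay there in 4, as often as Ank, and no enrichment was tested.

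The 1183 regions specific to either genotype compare with 9230 in the highest other split, which set WT replicate 1, HOM replicate 2 and HOM replicate 3 against the rest. For genes the values were 237 and 1873, from the same split. In each case 2 of the 10 splits gave a count at least as high, the real one included, and 10 splits are too few for a share under 0.05. That split parts the shorter lists from the longer ones, which by itself favours a high count. Its count several times the real one therefore cannot be read as a structure of the samples beyond list length. With HOM replicate 2 left out and 15184 peaks per list, the real split gave 671 regions and the highest other split, WT replicates 2 and 3 against the rest, 1362, with 5 of 10 splits at least as high as the real one. For genes the values were 140 and 257, with 6 of 10. At that peak number WT replicates 2 and 3 still covered the most, 14.2 and 24.2 Mb, so these splits were not free of covered length.

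HOM replicate 2 had 1462 peaks, of which 15.5% lay on unplaced sequences against at most 0.395% in the other libraries. Its background pileup was 0.387 times the mean of the other libraries, but 1.14 times when divided by the smallest peak width, so fewer sequenced tags stay open, depending on whether that width is the fragment length. At equal length, 7.11% of its peaks lay at gene ends against 9.51% or more elsewhere, so low enrichment of acetylated DNA is a candidate explanation. Its smallest peak width of 57 bp leaves a shorter fragment length in peak calling open: rescaled to it, WT replicate 1 would keep 20 peaks at gene ends against 104 in HOM replicate 2, but WT replicate 3 would keep 2374. This rescaling was planned for WT replicate 1 and extended to the other libraries after its value was seen, and an effect of the deletion was not tested.

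HOM replicates 1 and 3 both had peaks beside the interval where no WT library had any. Between positions 147969928 and 147985012 of chromosome 4 they had 5 and 3 peaks, and overlapping peaks of both made a region from 147981545 to 147982327, which ends 3458 bp from Nppb. The positions are the gap between neighbouring peaks of WT replicate 3, so the lack of WT peaks in it was set by that choice. The −log10 q of these peaks ran from 1.8 to 7.79 in HOM replicate 1 and from 2.4 to 3.84 in HOM replicate 3. The medians of those lists were 3.78 and 3.08, so several of the peaks were weak calls. Shorter WT lists are argued against by 2 WT lists that are longer than both HOM lists and lack a peak there. Of 7982 regions in both HOM libraries 25 lacked a WT peak, and within 50 kb of the interval 1 of 7 did (two-sided Fisher exact p = 0.0217); with 1 region, found before it was tested, calling noise unrelated to the locus stays open. A candidate explanation, that the deletion lets acetylation spread or brings other sequence next to these sites, may be followed up but was not tested.

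WT replicate 1 and HOM replicate 1, 1 library of each genotype, had 111 and 112 peaks on the Y chromosome below 80 Mb, and each other library had 5 or fewer. Animals of both sexes are a possible explanation, since the labels give no sex. At 15184 peaks per list, they had 45 and 28 X peaks (0.296% and 0.184%), against 0.349% to 0.678% in WT replicates 2 and 3 and HOM replicate 3. The gap between 0.296% and 0.349% is smaller than the SD of 0.165% among those 3 libraries, so the lower X share that both sexes would give cannot be told from the spread between libraries, and the explanation stays open.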
